A study of Mus musculus with 6 samples.

How the data were processed

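RNA sequencing of the cerebellum was deposited for 6 mice, 3 born to dams given MeHg and 3 controls. Per the labels the libraries were sequenced on an Illumina NovaSeq with paired-end reads of 150 bases. The submitters' processing notes name the mm39 reference and DESeq2. The aligner, the counting program, the annotation release and the strand handling are not given in the sources used here. The deposited gene table holds raw counts per gene, in whole numbers, with no normalisation. A second deposited table holds FPKM values, made by the authors from the counts, the gene length and a library total, with 2 further columns that are group means. The count table holds 56748 genes, of which 98.7% have an identifier in the GENCODE reference used here, and 92.0% of those start within 1000 bp of it. All columns were matched to a labelled sample.

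Libraries were grouped by the labels of exposure. Low counts were removed with edgeR's filterByExpr, which left 16859 genes, and library sizes were scaled by TMM. MeHg was compared with control in all 6 libraries by the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with the group as the only term. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. The SE of a log2 fold change is its absolute value divided by the square root of F. Levels are given as CPM, the count relative to the scaled library size. The sexes were compared in the same way with the group in the model, and the interaction with group, sex and their product.

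In all, 45 gene lists were written before the data were examined, as were the tests, the named-gene rule and the first set of alternatives. Of 982 listed symbols 18 were not matched to a symbol of the table. The sex-linked list served to check labels, the leukocyte list had fewer than 5 tested members, and the other 43 lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), which compares a list with all other genes. Each was also tested with a correlation estimated from the data and with fry, which does not compare a list with other genes. List p-values were adjusted over the 43 lists. A list score is the mean log2 CPM of its members in a library, compared by a two-sided exact permutation test.

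The genes named are those called with a mean of at least 1 CPM, without provisional Gm or Rik symbols: the 10 higher and 10 lower with the smallest p, and the 3 higher and 3 lower with the largest fold. To these come the 3 members with the smallest p of each list that passed, and 19 genes fixed for metal, selenium, cell type, blood, disease and time of day. For sex they are Xist, 4 Y-linked genes and the 3 genes off the sex-linked list with the smallest p, and for the interaction the 3 genes with the smallest p. Genes named outside this rule are said to be, and a few genes that the rule names are not reported.

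The alternatives chosen before the data were examined were DESeq2 size factors, upper-quartile scaling, other filters, sex or replicate number as a term, the libraries labelled female alone, leaving out each library, DESeq2 1.42.0, limma-voom, limma on log2 FPKM with 1 or 0.1 added, and other thresholds. Added after the data were seen were loess offsets per library for gene length, GC content or both, the choroid plexus score or the Xist level as a covariate, leaving out the 20 most abundant genes from the totals, and leaving out both libraries numbered 2. Length was taken from the deposited table and GC content from the longest transcript of each gene. With an offset, the log2 CPM behind list tests and scores appear to subtract it repeatedly, whereas the edgeR fold changes use it a single time. List tests and scores with an offset may therefore overcorrect.

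The procedure was tested on simulated data with changes planted in known genes. The edgeR test recovered 27 of 66 genes changed by 0.5 on the log2 scale, 39 of 66 changed by 1 and 58 of 64 changed by 2, with 10 false calls among 16428 unchanged genes. Camera called 2 of 2 planted lists and 0 of 41 others. The simulated genes varied independently, so this does not test camera on lists whose members vary together. Splits of the real libraries that mixed the groups gave up to 16 called lists. The interaction test recovered 150 of 195 genes planted at 3, with 27 false calls, and the sex test 179 of 194 planted at 2, with 16 false calls. No 2 libraries of a group were copies: the chi-square per degree of freedom between them was 7.77 to 19.69.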

Results

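RNA was sequenced from the adult cerebellum of 6 C57BL/6J mice, each 90 to 120 days old. The mothers of 3 of them had drunk water containing 0.2 ppm methylmercury (MeHg), an organic mercury compound that is toxic to neurons, throughout pregnancy. The mothers of the other 3, the controls, had drunk water with 0 ppm. By the labels each group held 2 females and 1 male. Control replicate 2, labelled female, had the Xist and Y-linked RNA levels of a male. By expression, sex was thus not balanced between the groups. No label gives the dam or the litter, so the p-values measure the spread between these 6 samples, and litter mates could not be told from unrelated mice. The total count was 20139080, 20303833 and 14116088 in control replicates 1, 2 and 3, and 15975367, 15271132 and 14487022 in MeHg replicates 1, 2 and 3. Of 56748 genes in the count table, 16859 had enough counts to be tested. On the first principal component of the 1000 most variable genes (48.3% of the variance), all controls scored negative and all MeHg libraries positive. MeHg replicate 2 and control replicate 1 lay at opposite ends of the second, with 32.1%. The first ran from -38.7 in control replicate 3 to 27.8 in MeHg replicate 3. These libraries also had the lowest and highest mean of choroid plexus markers (0.46 and 6.67 log2 CPM). The first component thus does not separate exposure from choroid plexus content.

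The first comparison asked whether dosing of the dams from conception to birth was followed by different RNA levels in the adult cerebellum of the offspring. Markers of granule cells, the most numerous neurons of the cerebellum, fell as a list in MeHg, with a median log2 fold change of -0.38 over 15 genes (adjusted p = 0.522 with an estimated correlation). Markers of ependymal cells, the ciliated cells that line the ventricles, rose as a list with a median of 1.18 over 9 genes (adjusted p = 0.522 with an estimated correlation). Genes for cytosolic ribosomal proteins (median 0.21 over 76 genes, 6 of them called) and nuclear genes of oxidative phosphorylation (0.19 over 76, 0 called by edgeR) rose by less as lists, each with an adjusted p of 0.585 with an estimated correlation. Genes for chromatin regulators fell as a list (-0.19 over 23, 3 called, camera adjusted p = 0.522 with an estimated correlation). With an offset for length their median was -0.10 and the list test made no call (camera adjusted p = 0.962). Across all genes 97 rose and 301 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted, 3 against 3), a 75.6% share of falls that was 49.5% of 2378 calls without a filter on low counts and 48.4% of 1640 calls with the Xist level as a covariate. The median absolute log2 fold change of the 398 genes was 0.44, and 32 of those that rose and 4 of those that fell changed at least 2-fold. In all 398 the 3 MeHg libraries lay on 1 side of the 3 controls, which held for 29.4% of all tested genes against 10% by chance. No adjusted p was below 0.0431, although 4132 genes had an unadjusted p under 0.05 where chance gives 843.

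The number of calls changed with the library left out: 0 passed without control replicate 1, control replicate 3 or MeHg replicate 3 (3042, 2572 and 3099 genes at an unadjusted p under 0.05), 2 without MeHg replicate 1, 220 without control replicate 2, 1091 without MeHg replicate 2 and 1723 without both libraries numbered 2, while DESeq2 called 1390, limma-voom 358 and limma on log2 FPKM 0. With upper-quartile scaling 78 genes rose and 119 fell, and with an offset for gene length and GC content the edgeR test called 0 genes (3559 at an unadjusted p under 0.05).

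**Figure D1:**
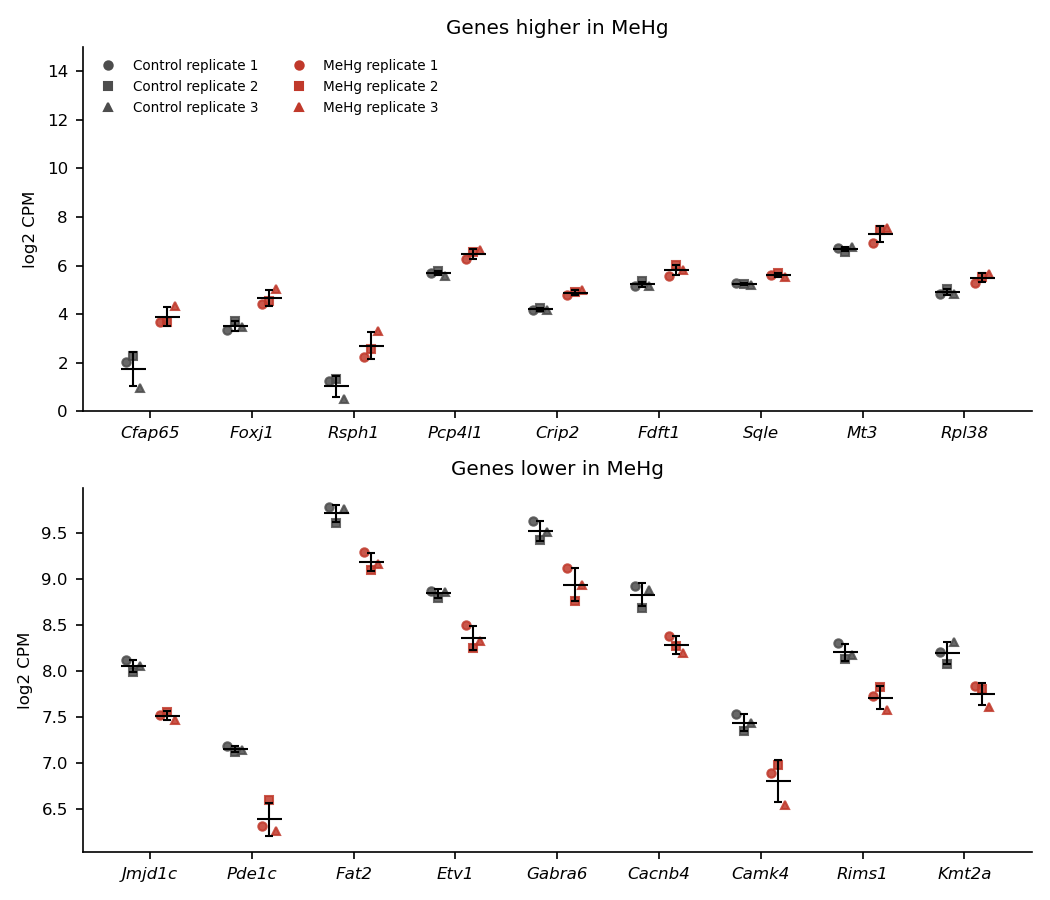
Level in log2 CPM (counts scaled to library size) of 9 genes that rose and 9 that fell in MeHg, on separate vertical scales. Each symbol is 1 library, and the bars are the mean and SD of 3; in each of the 18 genes the MeHg libraries lie on 1 side of the controls.

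Among the genes that rose with the smallest p were several of motile cilia. Foxj1, the transcription factor that switches on the motile cilium programme (chromosome 11, 116221530 to 116226225, mm39), was at 26.0 ± 6.27 CPM (SD, n = 3) in MeHg and 11.6 ± 1.65 CPM in controls, a log2 fold change of 1.17 ± 0.18 (SE, adjusted p = 0.0431). The axonemal genes Cfap52 and Cfap65 rose by 2.11 ± 0.31 and 2.05 ± 0.31, from 0.809 and 3.63 CPM in controls. Pcp4l1 rose by 0.80 ± 0.10 from 51.6 ± 3.24 CPM to 89.7 ± 12.1 CPM. Crip2 (0.69 ± 0.09), the basement membrane collagen Col4a2 (0.65 ± 0.10), Ubxn11 (0.99 ± 0.16) and Igfbp4 (0.77 ± 0.13) also rose. ENSMUSG00000095041, a protein-coding model on an unplaced scaffold at 52190 to 59690, rose by 1.13 ± 0.14. Its reads can be shared with similar copies, so its value is uncertain. The largest folds were those of Crhbp (2.37 ± 0.50) and Crhr2 (2.17 ± 0.47), a binding protein and a receptor of the corticotropin-releasing hormone family, and of the kinesin light chain Klc3 (2.26 ± 0.41), all under 1 CPM in controls.

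The genes that fell with the smallest p were moderately to highly expressed and changed by less. Jmjd1c, a JmjC-domain chromatin gene (chromosome 10, 66931904 to 67092105), fell by 0.54 on the log2 scale (SE 0.06, adjusted p = 0.0431) from 267 ± 11.5 CPM in controls to 183 ± 5.86 CPM in MeHg. The cyclic nucleotide phosphodiesterase gene Pde1c (chromosome 6, 56046789 to 56629472) fell by 0.75 (SE 0.09) from 142 ± 3.15 CPM to 84.4 ± 10.8 CPM. Falls were also called for Fam135b (-0.63), Alms1 (-0.66), Cemip (-0.64), the chromatin remodeller Chd7 (-0.53), Igsf9b (-0.53), Shprh (-0.48), Phip (-0.45) and the ceramide synthase Cers6 (-0.71), each with an adjusted p of 0.0431. The largest falls were those of Rtl10 (-1.38 ± 0.29), the long non-coding gene ENSMUSG00000121184 (-1.28 ± 0.22), annotated as sense intronic to Atp6v0a1, and the water channel gene Aqp5 (-1.27 ± 0.23), all under 7 CPM in controls.

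Granule cell markers fell as a list (camera adjusted p = 3.21e-08; adjusted p = 0.522 with an estimated correlation). All 15 had a negative fold change, 5 of them passed over all genes and 14 when adjusted over the list alone. Fat2, a protocadherin of granule cells, fell from 844 ± 53.6 CPM to 585 ± 41.6 CPM (-0.53 ± 0.08). Gabra6, a GABA receptor subunit restricted to granule cells within the cerebellum (chromosome 11, 42197264 to 42211899), fell from 738 ± 55.6 CPM to 495 ± 61.6 CPM (-0.58 ± 0.10), and Etv1 fell by 0.48 (SE 0.08). Markers of other cerebellar neurons did not pass as lists: Purkinje cells (15 genes, median -0.17, adjusted p = 0.193), interneurons (14 genes, 0.03, 0.649) and unipolar brush cells (8 genes, -0.32, 0.0903). The Purkinje cell genes Pcp2 (0.06 ± 0.15) and Calb1 (-0.20 ± 0.13) did not pass. The mean log2 CPM of the granule list was 8.78 ± 0.11 (SD) in MeHg and 9.14 ± 0.06 in controls, a difference of -0.37 ± 0.07 (SE, two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows).

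Calcium channel and calcium handling genes fell as a list of 33 (median -0.12, camera adjusted p = 0.000722, and 0.585 with an estimated correlation). With an offset for length their median was -0.06 and the list test made no call (camera adjusted p = 0.605). The channel subunit Cacnb4 (-0.55 ± 0.08), the ryanodine receptor Ryr2 (-0.51 ± 0.09) and the kinase Camk4 (-0.62 ± 0.10) were among the 6 that fell. Adjusted over the list alone, 13 fell and 1 rose. The 27 synaptic vesicle genes also fell as a list (median -0.09, adjusted p = 0.0475; adjusted p = 0.625 with an estimated correlation), with a median of -0.02 (adjusted p = 0.605) with an offset for length and -0.05 (0.214) with 1 for length and GC content, and 4 of them passed, among them the active zone scaffolds Rims1 (-0.49 ± 0.08), Pclo (-0.44 ± 0.08) and Bsn (-0.52 ± 0.10). Adjusted over the list alone, 7 fell and 1 rose, and the list mean was higher in MeHg replicate 2 than in any control (two-sided exact permutation p = 0.4). Glutamate receptor and transporter genes (31 genes, median -0.17, adjusted p = 0.155), GABA and glycine signalling genes (25 genes, -0.06, 0.236) and tubulin and cytoskeleton genes (28 genes, 0.05, 0.236) did not pass as lists. For the GABA list the mean was 0.12, opposite in sign to the median and the test.

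Genes of DNA methylation and chromatin fell as a list of 23 (median -0.19, camera adjusted p = 0.000303, and 0.522 with an estimated correlation). With an offset for length their median was -0.10 and the list test made no call (camera adjusted p = 0.962). The methyltransferase Kmt2a (-0.45 ± 0.08), the remodeller Chd8 (-0.31 ± 0.06) and the methylcytosine dioxygenase Tet3 (-0.31 ± 0.06) passed over all genes, and 12 fell when adjusted over the list alone. Circadian clock genes fell as a list of 19 (-0.13, camera adjusted p = 0.0220, and 0.522 with an estimated correlation, 0.229 with an offset for length and 0.169 with 1 for length and GC content). Their median was -0.12 with either of these offsets. The nuclear receptor Rora passed (-0.31 ± 0.07), Per2 (-0.64 ± 0.15) did not, and 4 fell when adjusted over the list alone. Glucocorticoid response genes (15 genes, -0.28, adjusted p = 0.0277; adjusted p = 0.604 with an estimated correlation) and unfolded protein response genes (27 genes, -0.21, adjusted p = 0.0279; adjusted p = 0.609 with an estimated correlation and 0.0504 with an offset for GC content) fell as lists with 0 members passing the edgeR test over all genes. Adjusted over the list alone, 2 and 3 of their members fell. The mean log2 CPM of both lists was lowest among controls in replicate 2: at 4.52 it lay below MeHg replicate 1 (4.74) for the glucocorticoid list, and at 5.66 below all 3 MeHg libraries for the unfolded protein response list (two-sided exact permutation p = 0.2 and 0.4). Zbtb16 (-1.19 ± 0.30), Klf9 (-0.37 ± 0.09) and Cdkn1a (-0.68 ± 0.31) of the first list, and the endoplasmic reticulum chaperones Sdf2l1 (-0.87 ± 0.19) and Hsp90b1 (-0.42 ± 0.10) and the factor Xbp1 (-0.62 ± 0.15) of the second, had the smallest p. The heat shock list (19 genes, -0.15, adjusted p = 0.193), the immediate early list (19 genes, -0.33, 0.359; 0.0495 with an offset for length and GC content) and the thyroid hormone list (15 genes, -0.22, 0.236) did not pass. The mean of the thyroid list was 0.01, opposite in sign to its median. Fos (-0.62 ± 1.02), Per1 (-0.42 ± 0.24) and Dbp (0.22 ± 0.24) did not pass.

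**Figure D2:**
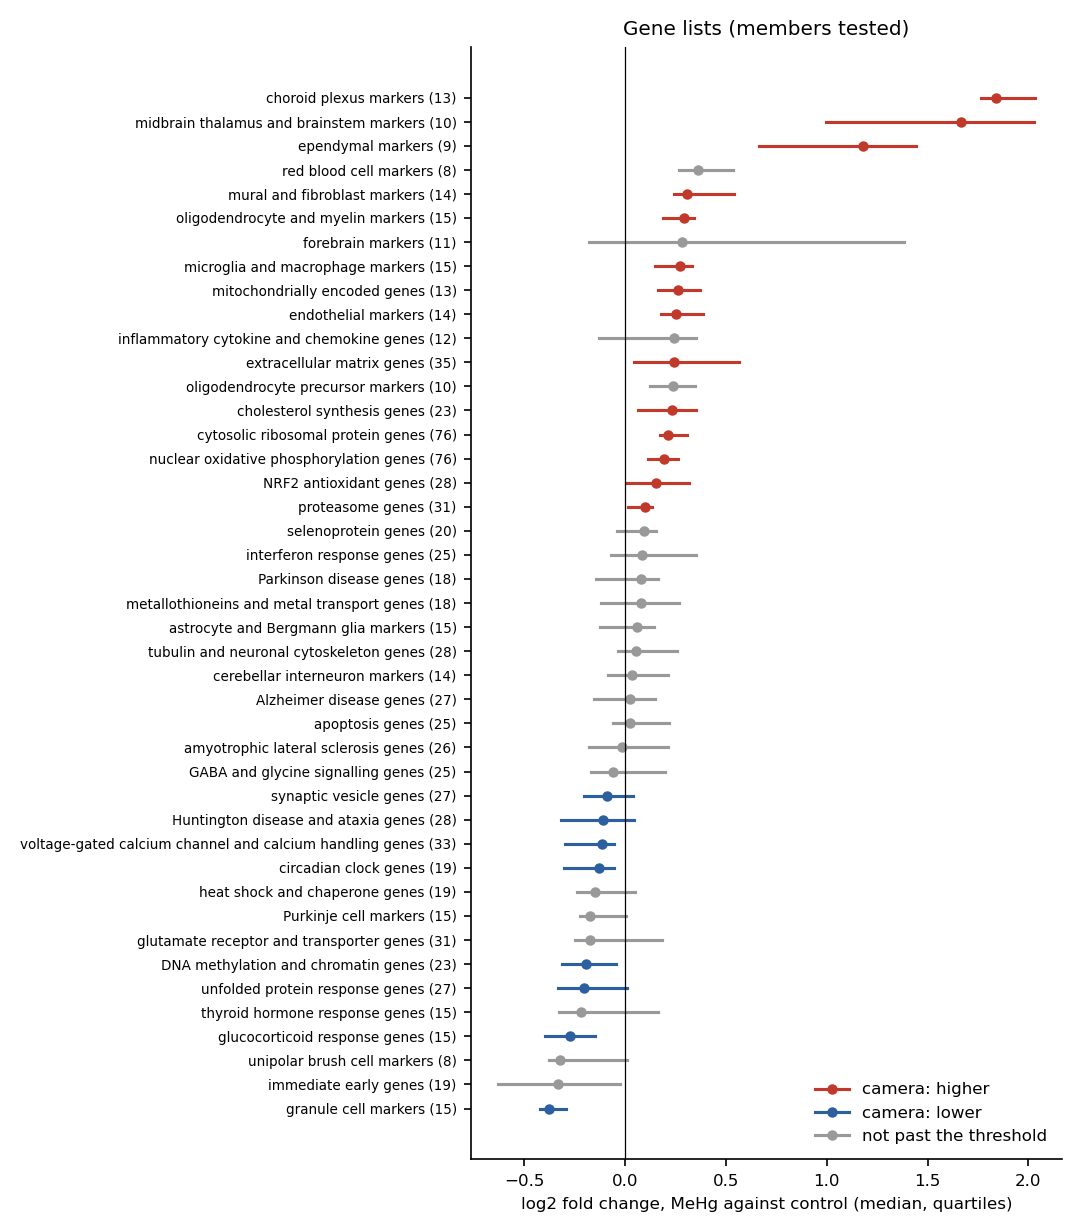
Median and quartiles of the log2 fold change, MeHg against control, over the tested members of 43 gene lists, with the number tested in brackets. Of these, 14 lists passed upward and 8 downward with camera's preset correlation, from a median of 1.84 for choroid plexus to -0.38 for granule cells.

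Several lists for tissue next to the cerebellum were higher in MeHg. Ependymal markers rose (adjusted p = 1.42e-05; adjusted p = 0.522 with an estimated correlation). Foxj1 and Rsph1 (1.68 ± 0.32), a radial spoke protein of cilia, passed, 7 others did not, and 8 rose when adjusted over the list alone. Cfap126, at 1.66 ± 0.36, had an adjusted p of 0.0502. Choroid plexus markers rose as a list of 13 (median 1.84, adjusted p = 0.000303; adjusted p = 0.585 with an estimated correlation), but 0 members passed with edgeR, over all genes or adjusted over the list alone. Their mean log2 CPM was 5.16, 3.39 and 0.46 in control replicates 1, 2 and 3 and 5.60, 4.78 and 6.67 in the MeHg replicates (two-sided exact permutation p = 0.2). Ttr, the thyroxine carrier made by choroid plexus, was at 3462 ± 2588 CPM in MeHg and 702 ± 918 CPM in controls (2.30 ± 1.29, adjusted p = 0.306), and Otx2 (0.85 ± 0.30), Aqp1 (2.03 ± 0.74) and Slc4a5 (2.02 ± 0.76) did not pass. Markers of midbrain, thalamus and brainstem rose as a list of 10 (1.67, adjusted p = 0.00756; adjusted p = 0.585 with an estimated correlation), and 1 member passed, when adjusted over the list alone. Their mean log2 CPM was 1.07, 2.03 and 1.31 in control replicates 1, 2 and 3 and 1.32, 4.31 and 2.50 in the MeHg replicates (two-sided exact permutation p = 0.2). Tph2, the serotonin synthesis enzyme of raphe neurons, was at 67.5 CPM in MeHg replicate 2 and at 0.203 to 1.48 CPM in the other 5 libraries (5.36 ± 1.68, adjusted p = 0.105). Slc5a7 (2.69 ± 0.96) and Lef1 (0.87 ± 0.23) did not pass over all genes either. Lef1 had the smallest p of the list and was the member that passed when adjusted over the list alone. Forebrain markers (11 genes, 0.28, adjusted p = 0.236) and red blood cell markers (8 genes, 0.36, 0.154; Hba-a1 0.39 ± 0.32) did not pass.

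**Figure D3:**
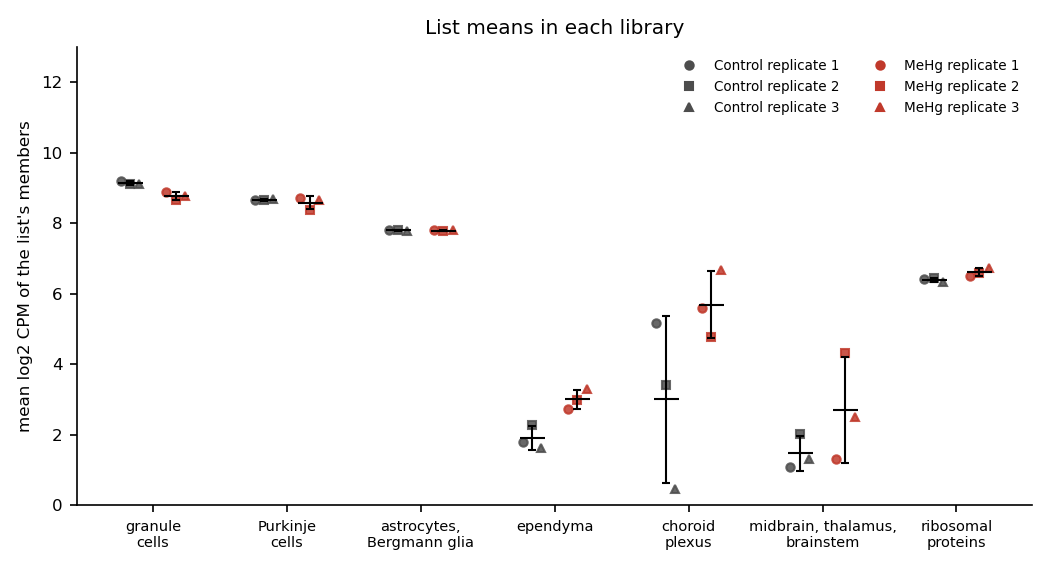
Mean log2 CPM over the members of 7 gene lists in each library, with the mean and SD of 3 libraries per group. The granule list lies lower and the ependymal list higher in all 3 MeHg libraries, and the choroid plexus list runs from 0.46 in control replicate 3 to 6.67 in MeHg replicate 3.

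Vascular and glial lists rose by smaller amounts. Endothelial markers (14 genes, median 0.25, adjusted p = 0.00101), oligodendrocyte and myelin markers (15 genes, 0.29, 0.00101), mural cell and fibroblast markers (14 genes, 0.31, 0.00177) and microglia markers (15 genes, 0.27, 0.00154) passed, each with an adjusted p = 0.585 with an estimated correlation. With an offset for length, and with 1 for length and GC content, the microglia list lost its call (camera adjusted p = 0.231 and 0.285, median 0.20 and 0.17) and the other 3 kept theirs. Of these 4 lists only the endothelial receptor gene Flt1 passed over all genes (0.44 ± 0.09, adjusted p = 0.0440), and 4, 2, 3 and 0 members rose when adjusted over the list alone. Slco1c1 (1.05 ± 0.31), Itm2a (0.31 ± 0.10), Mag (0.40 ± 0.10), Trf (0.26 ± 0.07), Mobp (0.35 ± 0.11), Pdgfrb (0.48 ± 0.13), Rgs5 (0.29 ± 0.08), C1qa (0.30 ± 0.10), Ctss (0.32 ± 0.11) and Csf1r (0.26 ± 0.10) did not pass. The mean log2 CPM of the endothelial list was highest in MeHg replicates 1 and 3 (5.04 and 5.15), as was that of the mural list (4.36 and 4.39), which at 3.87 in MeHg replicate 2 lay below the 4.02 of control replicate 1 (two-sided exact permutation p = 0.2). The oligodendrocyte list was highest in MeHg replicate 2 (7.54), the library with the highest brainstem list, against 7.16 and 7.23 in MeHg replicates 1 and 3 and at most 7.13 in controls. Mbp was at 0.29 ± 0.13 (adjusted p = 0.200). Extracellular matrix genes rose as a list of 35 (0.24, adjusted p = 0.00114; adjusted p = 0.522 with an estimated correlation), with Col4a2 passing over all genes and 5 rising when adjusted over the list alone. Lum (0.89 ± 0.20) and Acan (1.16 ± 0.27) did not pass. Astrocyte and Bergmann glia markers did not pass (15 genes, median 0.06, mean 0.01, test downward, adjusted p = 0.993), nor did Gfap (0.25 ± 0.09), oligodendrocyte precursors (10 genes, 0.24, 0.154), cytokines and chemokines (12 genes, 0.24, 0.193), interferon response (25 genes, 0.08, 0.236) or apoptosis genes (25 genes, median 0.02, mean 0.13, 0.390). The cytokine and apoptosis list means were higher in all 3 MeHg libraries than in any control (two-sided exact permutation p = 0.1 for each, the smallest possible). Those of the astrocyte, precursor and interferon lists overlapped.

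Ribosomal protein genes rose as a list (camera adjusted p = 3.12e-12; adjusted p = 0.585 with an estimated correlation), with 71 of 76 fold changes positive, 6 passing over all genes and 47 when adjusted over the list alone. Rpl38 (0.60 ± 0.11) and Rps2 (0.34 ± 0.06) had the smallest p. Ribosomal protein genes have many near-identical pseudogenes, so their single values are uncertain. Nuclear oxidative phosphorylation genes rose as a list (camera adjusted p = 1.3e-09, and 0.585 with an estimated correlation, 0.401 with an offset for length and 0.262 with 1 for length and GC content). Of the 76 fold changes 73 were positive, with 0 passing the edgeR test over all genes and 16 when adjusted over the list alone. The median was 0.12 with either of these offsets. Ndufa8 was at 0.35 ± 0.08, Atp5d at 0.26 ± 0.06 and Cox5b at 0.33 ± 0.08. The 13 mitochondrially encoded genes rose as a list (median 0.26, camera adjusted p = 0.0451, and 0.609 with an estimated correlation). Camera's adjusted p was 0.753 with an offset for length, 0.0495 with 1 for length and GC content and 0.000426 with 1 for GC content. Of the members 0 passed either way, and the list means overlapped (two-sided exact permutation p = 0.3). The smallest p were those of mt-Nd4l (1.14 ± 0.34), mt-Nd1 (0.37 ± 0.15) and mt-Nd4 (0.29 ± 0.14). The 31 proteasome genes rose (0.10, camera adjusted p = 0.0220, and 0.585 with an estimated correlation) with 0 passing either way. With an offset for length their median was 0.03 and the list test made no call (camera adjusted p = 0.459). Psmb1 was at 0.18 ± 0.06, Psmb4 at 0.18 ± 0.07 and Psmc5 at 0.15 ± 0.06.

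Cholesterol synthesis genes rose as a list of 23 (0.23, adjusted p = 0.00101; adjusted p = 0.522 with an estimated correlation). The squalene synthase Fdft1 (0.59 ± 0.12) and the squalene epoxidase Sqle (0.37 ± 0.08) were among the 4 that passed, and 8 rose when adjusted over the list alone. The 28 antioxidant genes controlled by NRF2 rose as a list (0.15, camera adjusted p = 0.00756, and 0.522 with an estimated correlation, 0.149 with an offset for length and 0.184 with 1 for length and GC content). Their median was 0.11 and 0.10 with these offsets. None passed over all genes with edgeR, and adjusted over the list alone 9 rose and 1 fell. Cbr1 (0.33 ± 0.07), Sod1 (0.31 ± 0.07) and Gsta4 (0.40 ± 0.11) had the smallest p. Metallothionein and metal transport genes did not pass as a list (18 genes, 0.08, adjusted p = 0.333). Within it Mt3, the metallothionein of neural tissue (chromosome 8, 94879235 to 94880774), rose from 103 ± 6.80 CPM to 163 ± 34.4 CPM (0.65 ± 0.14, adjusted p = 0.0491). Mt1 was at 0.02 ± 0.07 and Mt2 at -0.33 ± 0.25. Selenoprotein genes, whose products bind mercury through selenium, did not pass as a list (20 genes, 0.09, camera adjusted p = 0.193). The means of the selenoprotein and metal lists were nonetheless higher in all 3 MeHg libraries than in any control (two-sided exact permutation p = 0.1 for each, the smallest possible). Gpx1 (0.28 ± 0.18), Gpx4 (0.28 ± 0.06, adjusted p = 0.0545) and Selenop (0.09 ± 0.06) did not pass.

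Of 4 lists of genes tied to neurodegenerative disease, named in the title of the series, 1 passed. Huntington disease and ataxia genes fell as a list of 28 (median -0.11, camera adjusted p = 0.0315, and 0.585 with an estimated correlation). With an offset for length their median was -0.07 and the list test made no call (camera adjusted p = 0.854). The transcription factor Tbp (-0.41 ± 0.09) and the calcium channel Cacna1a (-0.40 ± 0.09) passed, both mutated in spinocerebellar ataxias, and the ataxia telangiectasia kinase Atm (-0.60 ± 0.14, adjusted p = 0.0545) did not. Adjusted over the list alone, 8 fell and 2 rose, and the list means of the groups overlapped (two-sided exact permutation p = 0.2). Alzheimer disease genes (27 genes, median 0.02, mean 0.05, test downward, adjusted p = 0.733), Parkinson disease genes (18 genes, 0.08, 0.784) and amyotrophic lateral sclerosis genes (26 genes, median -0.01, mean 0.05, test downward, 0.554) did not pass. Adjusted over the list alone, 1 rose and 2 fell, 0 rose and 2 fell, and 2 rose and 5 fell in these lists. App (0.07 ± 0.08) and Mapt (-0.18 ± 0.08) did not pass.

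The fold changes followed transcript length and GC content. The genes that fell had a median length of 10325 bp and a median GC content of 45.3%, against 3469 bp and 54.0% for those that rose and 4105 bp and 49.2% for all tested genes. From the shortest to the longest length decile of genes the median log2 fold change went from 0.10 to -0.14, and the longest decile held 171 of the 301 genes that fell. The slope on GC content of log2 CPM relative to the mean of the 6 libraries, in log2 units per change from 0 to 1 in the GC fraction, was -0.375, -0.558 and -0.482 in control replicates 1, 2 and 3 and 0.567, 0.436 and 0.412 in the MeHg replicates. The opposite signs follow from taking that mean as the reference, and the difference between the groups was 0.943 ± 0.0715 (SE, two-sided exact permutation p = 0.1, the smallest possible). Across genes, which are not independent replicates, Spearman's rho of the fold change was -0.210 with length and 0.195 with GC content.

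**Figure D4:**
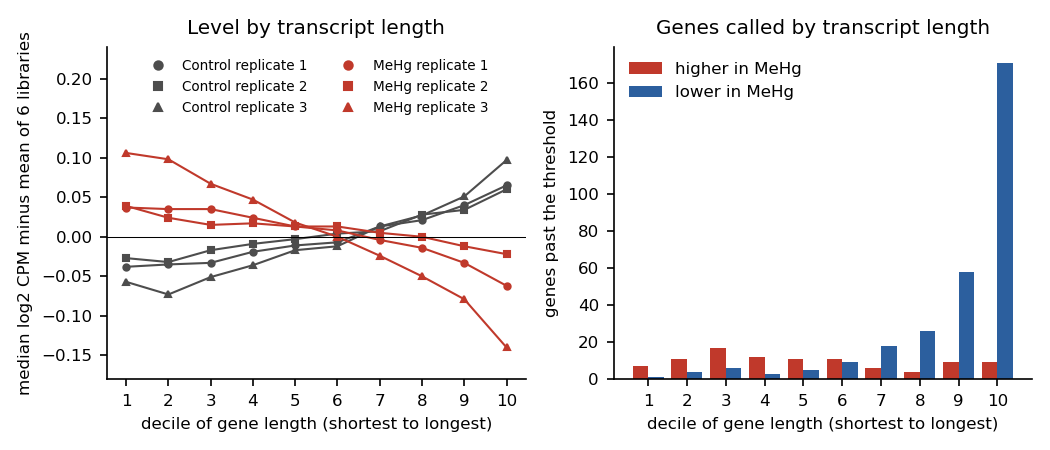
Left, median log2 CPM relative to the mean of the 6 libraries in each decile of the genes by length; right, the number of genes that rose or fell in MeHg in each decile. The MeHg libraries lie above the controls in the shortest decile and below them in the longest, which holds 171 genes that fell.

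The second comparison asked how males and females differed and checked the sex labels. Xist, the RNA that coats the inactive X chromosome, was at 772, 748 and 694 CPM in control replicate 1, MeHg replicate 1 and MeHg replicate 3, all labelled female. In the library labelled control replicate 2, also labelled female, Xist was at 0.249 CPM, and the Y-linked genes Ddx3y (87.2 CPM), Eif2s3y (59.4), Kdm5d (45.1) and Uty (23.9) were at the levels of the 2 libraries labelled male. Ddx3y was at 81.7 and 86.5 CPM in those 2 libraries and had 0 counts in the other 3 libraries labelled female. With the labels as given and the exposure group in the model, edgeR called 0 genes between the sexes (1019 at an unadjusted p under 0.05, 843 by chance). Off the sex-linked genes, Nktr (0.36 ± 0.07, male against female), the potassium channel Kcnk9 (0.55 ± 0.11) and Dnai3 (-1.71 ± 0.33) had the smallest p and did not pass (adjusted p = 0.818). Without the library labelled control replicate 2 the test called 21 genes, Xist (-12.72 ± 0.19), Ddx3y, Eif2s3y, Kdm5d and Uty among them, and without control replicate 3 it called 166. DESeq2, with all 6 libraries, called 5 genes, named here after their values were seen: Xist, Kcnk9, Sostdc1, Folr1 and Calml4. The 2 libraries labelled male had the lowest choroid plexus means of their groups (0.46 and 4.78 log2 CPM). One of them, MeHg replicate 2, had the highest brainstem mean (4.31). Tph2 and Slc17a6 of the brainstem list were among the 21 genes. Sex and adjoining tissue thus cannot be told apart for genes of such tissue.

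**Figure D5:**
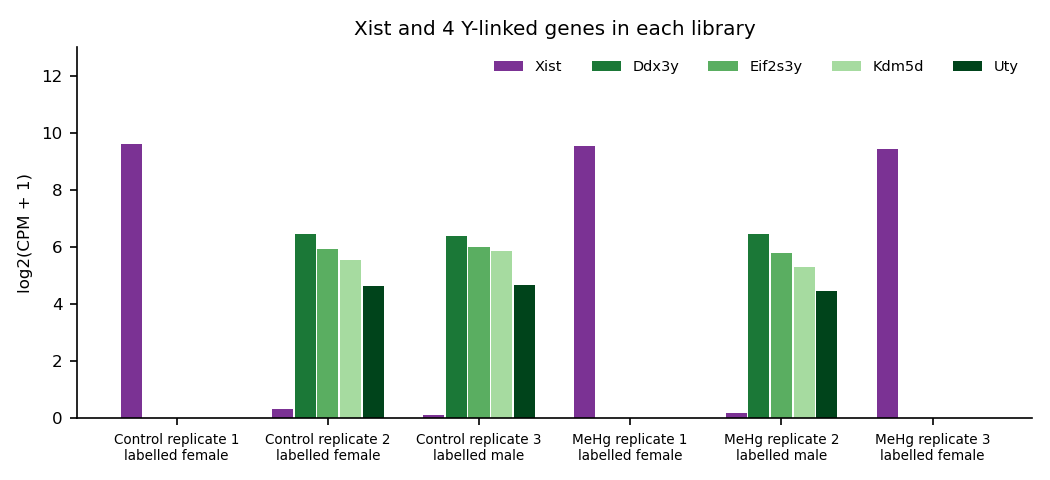
Level, as log2(CPM + 1), of Xist and 4 Y-linked genes in each library under its sex label. The library labelled control replicate 2 is labelled female and has the Y-linked levels of the males, with Ddx3y at 87.2 CPM.

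The third comparison asked whether the exposure difference itself depended on sex. Each group has 1 male library by the labels, so the spread comes from the libraries labelled female, of which control replicate 2 has the Xist and Y-linked levels of a male. On simulated data with 195 planted genes this test made 27 false calls among 16427 unchanged genes. That number belongs to the simulation, where 150 planted genes passed, and does not carry over to these data. In all, 3 genes passed the edgeR test of the interaction, the male log2 difference minus the female one. Ddc, the decarboxylase that makes dopamine and serotonin (chromosome 11, 11764101 to 11848144), had an interaction of 3.37 ± 0.32 (SE, adjusted p = 0.0196). It was at 51.6 CPM in MeHg replicate 2, the exposed male, and at 3.75 to 5.39 CPM in the other 5 libraries. In the same library Tph2 and the brainstem list were highest. Slc2a13, a myo-inositol transporter (chromosome 15, 91151899 to 91457464), had an interaction of 1.28 ± 0.14 (adjusted p = 0.0305), with 50.3 and 45.3 CPM in the exposed females, 117 CPM in the exposed male and 130 to 132 CPM in the controls. Gm29216, an unprocessed pseudogene whose reads can be shared with a copy elsewhere, had an interaction of 2.09 ± 0.20 (adjusted p = 0.0196), with 23.4 and 21.0 CPM in the exposed females and 91.0 CPM in the exposed male. DESeq2 called 34 genes, and the edgeR count was 563 without control replicate 1, 212 without the library labelled control replicate 2, 6 without MeHg replicate 1 and 26 without MeHg replicate 3.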

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

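The tests of other splits, of the granule list, of the ependymal list and of oxidative phosphorylation genes were chosen after the results were seen, as were the offset and the setting without the 20 most abundant genes. The bounds for the genes that fell, the ribosomal genes and the choroid plexus list were set before the values they apply to were seen.

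Ddc (3.37), Gm29216 (2.09) and Slc2a13 (1.28) passed the edgeR test of the interaction of exposure and labelled sex, as log2 differences. A difference between the sexes is not shown by this, since each group has 1 library labelled male and the library labelled control replicate 2, counted as female, has male Xist and Y-linked levels. The library total implied by the FPKM table lay 8.44 ± 0.51% (SD, n = 3) above the sum of the counts in MeHg and 4.73 ± 0.71% above it in controls (two-sided exact permutation p = 0.1, the smallest possible). The comparisons on counts do not use that table, and the limma alternatives on log2 FPKM do.

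The first pattern is the fall of 301 genes in MeHg, granule cell markers among them. Dilution by other tissue alone would lower granule and Purkinje markers alike if that tissue expressed neither list, which was not tested. The granule minus Purkinje score differed between MeHg and control by -0.276 (SE 0.07, two-sided exact permutation p = 0.1, the smallest possible). Under that assumption this argues against dilution as the whole cause, in a test chosen after both lists were seen. The Purkinje list held 1 gene called higher, and its mean fold change (-0.08) lay above its median (-0.17). MeHg replicate 2, with the highest brainstem list, had the lowest granule and Purkinje scores (8.665 and 8.365), so dilution in part stays open. For the granule list the tables argue against length and GC content as the whole cause: its median was -0.36 with that offset, -0.38 without. For the 301 genes as a set this trend cannot be told apart from the exposure: their median went from -0.42 to -0.30 with the offset, 71.0% of its size against a bound of 75% set beforehand, and the median SE from 0.08 to 0.07. The folds thus shrank by a larger share than their SE did, 301 of 301 stayed negative, and the smallest adjusted p was 0.0738. The real split gave 398 genes and 22 lists and the highest other split 6 genes and 16 lists; as large a result came from 1 of 10 splits for each, and 10 splits are too few for a share under 0.05. Exposure, litter and a difference in RNA quality or library preparation remain open and were not tested. By expression the sexes were also uneven between the groups. With the Xist level as a covariate edgeR called 1640 genes, and sex as a part of the cause stays open.

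The second pattern is the higher choroid plexus and ependymal lists. Within groups the other choroid plexus markers deviated with Ttr at a median r of 0.972 (lowest 0.846, 95th percentile of 1000 random lists 0.292), which is consistent with different amounts of adjoining choroid plexus in the dissected pieces. A single library is argued against, since the smallest choroid plexus median without 1 library was 1.29 (without MeHg replicate 3). For the ependymal markers the median r was 0.323, above that percentile and well below the choroid plexus value, so adjoining tissue stays open for them. Of the 13 choroid plexus markers 1, Otx2, is also in another list, and 0 of the 9 ependymal markers are.

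The third pattern is the small rise of ribosomal protein and oxidative phosphorylation genes, which are short. Without the 20 most abundant genes in the totals the ribosomal median moved by 0.00738, about as much as the median of all genes (0.00706), so that setting rescales all genes alike and decides nothing about abundant genes, although a bound of 0.05 had been set for it. With the length and GC offset the median was 0.153 for ribosomal genes and 0.12 for oxidative phosphorylation genes. The ribosomal value is just above 0.15, the bound set beforehand for arguing against the trend. The scores that follow were to be weighed against their SE by a rule chosen afterwards. The ribosomal list still passed camera (adjusted p = 0.0181) and the oxidative phosphorylation list did not (adjusted p = 0.262). The mean scores fell further, from 0.22 (SE 0.08) to 0.07 (SE 0.05) and from 0.18 (SE 0.06) to 0.05 (SE 0.03). Camera and the scores appear to subtract the offset repeatedly, so neither decides how much a single correction leaves. The ribosomal median met its bound narrowly, with no spread over libraries beside it. For both lists a trend with length and GC content and an effect of the exposure thus cannot be told apart.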

How the results depend on the processing

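The tests with offsets, the choroid plexus and Xist covariates, without the 20 most abundant genes and without both libraries numbered 2 were chosen after the results were seen. Sex as a covariate was the sex label, which the Xist and Y-linked levels of control replicate 2 contradict. For MeHg versus control genes the 398 calls became 197 with upper-quartile scaling, 2378 without a filter, 609 with sex as a covariate, 648 with a replicate block (no label says that the numbers pair the samples), 166 in libraries labelled female, 58 with a GC offset, 1640 with the Xist covariate and 1723 without both libraries numbered 2. The edgeR count was 0 with a length offset (3589 at an unadjusted p under 0.05), a length and GC offset (3559) and the choroid plexus covariate (1918), and DESeq2 gave 1390, limma-voom 358 and limma on log2 FPKM 0 with 1 added (3874) or 0.1 added (3887). Adjusted p under 0.1 gave 1653, unadjusted p under 0.05 gave 4132 and a 2-fold minimum 36. Leaving out 1 library gave 0 to 1091: 0 without control replicates 1 or 3 or MeHg replicate 3, 2 without MeHg replicate 1, 220 without control replicate 2 and 1091 without MeHg replicate 2. Of 22 lists, 12 passed with a length offset, 13 with length and GC (14 lists in all, with immediate early genes) and 20 with a GC offset (not unfolded protein response or Huntington disease and ataxia). The count was 10 with the choroid plexus covariate, 0 with an estimated correlation and 2 with fry. Fry called NRF2 antioxidant and chromatin genes (both at an adjusted p of 0.0499), and the granule list was at 0.0573. Without 1 library 16 to 19 of the 22 kept their call. With the length offset proteasome (median 0.0346), Huntington disease and ataxia (-0.0733, and -0.107 with length and GC), calcium (-0.064) and DNA methylation and chromatin genes (-0.103) lost their call. Their camera direction changed, at adjusted p of 0.459 to 0.982, while their median folds kept their sign, so no reversal is shown. List tests with offsets may overcorrect, so a lost call does not show that a single correction removes the difference. Between the sexes DESeq2 gave 5 genes, and edgeR 0 to 166 without 1 library: 1 without control replicate 1, 21 without 2 and 166 without 3. For the interaction DESeq2 gave 34, and edgeR 6 to 563: 563 without control replicate 1, 212 without control replicate 2, 6 without MeHg replicate 1 and 26 without MeHg replicate 3. For offsets, covariates and scalings the cause was not tested. Of the values of named genes under alternatives, 1851 kept their side of the threshold, 563 lost it and 151 gained it, and no called one changed direction. Depth was 14116088 to 20303833 counts, and at this size simulated changes of 0.5 were recovered in 40.9%.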

Other observations

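The test of the axonemal gene families was chosen after the results were seen, and all other values here were also picked after they were seen. Genes of the motile cilium recurred among those higher in MeHg. Of 67 tested genes in 7 families (symbols starting with Cfap, Dnah, Dnai, Dnaaf, Rsph, Drc or Tekt), 6 rose and 0 fell by the edgeR test: Cfap52, Cfap65, Dnah2 (1.29), Dnah10 (1.54), Rsph1 and Cfap44 (1.35). Of these 6, 5 are outside the ependymal list. In the families 8.96% rose against 0.542% of 16792 other genes, an odds ratio of 18.04 (95% interval 6.21 to 43.0, two-sided Fisher's exact test across genes, p = 2.33e-06; genes are not independent replicates). The families were chosen because called members had been seen, so these values describe that observation and do not test it. Without the 4 members already named in the comparison of MeHg with control, 3 of 63 rose. The fold change was positive in 59 of 67, with a median of 0.68. Their mean log2 CPM was 1.88, 2.02 and 1.63 in control replicates 1, 2 and 3 and 2.35, 2.54 and 2.73 in the MeHg replicates. Within groups they deviated with Ttr at a median r of 0.292, about the 95th percentile of 1000 random lists (0.292). Adjoining tissue thus stays open for them too.

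Among 12077 genes with a mean above 5 CPM, 78 were over 2-fold above every other library in MeHg replicate 2. That count was 16 in MeHg replicate 3, 1 in control replicate 3 and 0 in the other 3 libraries. Over 2-fold below every other library were 36 genes in control replicate 3 and 15 in control replicate 1. This lower count was 4 in MeHg replicate 3, 2 in control replicate 2, 1 in MeHg replicate 1 and 0 in MeHg replicate 2. Which kinds of gene make up the 78 was not tested. As single examples, Slc18a2, the vesicular monoamine transporter, was at 60.7 CPM there and at 4.77 to 10.5 CPM elsewhere, the noradrenaline transporter Slc6a2 at 21.4 CPM, and tyrosine hydroxylase, Th, at 33.6 CPM against 7.69 to 11.7 CPM.

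Immediate early genes, induced by neuronal activity, were mostly low in both libraries numbered 2: in 14 of the 19 members of the list both lay below the other 4 libraries, and Arc and Ier5 were among those where they did not. Fos was at 94.95, 3.34 and 91.7 CPM in control replicates 1, 2 and 3 and at 32.3, 4.65 and 86.2 CPM in the MeHg replicates, and Npas4 at 12.8, 1.95 and 12.2 CPM and at 4.45, 1.96 and 7.08 CPM. Nr4a1 was at 80.3, 14.4 and 87.0 CPM and at 37.9, 14.7 and 67.8 CPM. Over the 6 libraries Ttr and the other choroid plexus markers had a Pearson r of 0.986 (exact permutation p = 0.00139) and a Spearman rho of 1 (exact permutation p = 0.00278), with r = 0.996 without the 2 farthest libraries.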
